A study of Mus musculus with 6 samples.

How the data were processed

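Total RNA of cultured mouse dermal fibroblasts treated with IL-1 (20 ng/ml; 0, 1, 2 or 4 h) was labelled and hybridised to Agilent 2-colour arrays, per the labels' protocols. Each of the 6 arrays holds treated RNA of 1 time point in one dye and untreated RNA in the other. Replicate 1 has the treated RNA in Cy5 and replicate 2 has it in Cy3. Per the series' design text the duplicates are a dye swap, so the 2 arrays of a time point count as 1 sample and their spread is technical. Whether the untreated RNA is 1 extract on all arrays is not stated. It is the control and the common reference, and a ratio against 0 leaves out the control's own spread.

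Per the file headers the spots were read with Agilent Feature Extraction 7.5.1, and the intensity columns hold each spot's mean brightness and its local background before correction. The processed intensity columns were background-subtracted with spatial detrending and dye-normalized by a linear and lowess method, per the file headers. The p-value of each spot's log ratio comes from the software's error model, per the file headers. The value table deposited by the authors holds log2 ratios. Set against the scanner files, each column equals the log2 ratio of treated over untreated processed signals of the other array of the same time point, for 100% of spots within a tolerance of 0.001, so the 2 columns of each pair are exchanged. The scale is thereby settled, and no further centring was applied. The direction rests on the dyes in the labels, since the match does not show which source is exchanged. If the columns are, pair means are unaffected. If the scanner files are, every log2 ratio given here changes sign. In the labelled direction 16 of 19 measured NF-kB pathway genes rose in the mean response and 0 fell. Exchanged scanner files would turn these rises into falls after IL-1, an activator of NF-kB, so these genes argue against that case. The column medians were -0.026 and 0.0261 at 1 h, -0.0309 and 0.0311 at 2 h, and -0.0325 and 0.0283 at 4 h.

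Each array has 43790 spots, of which 2256 are controls. Mean signals were corrected with normexp (offset 50) and normalized within arrays by loess with limma 3.58.1 in R 4.3.3, controls having weight 0. Control spots and outlier flags were left out, saturated spots were kept, and spots of a probe were averaged. A probe was kept if well above background on every array of at least 1 of the 4 conditions, in the channel with that RNA, which left 30634 of 41174 probes; 54 of these had no value on some array and were dropped. The flag is permissive. Of 314 negative control spots, up to 14.3% in Cy3 and 2.5% in Cy5 carried it on a single array. Median signals were 124.3 to 137.7 in Cy5 and 121.8 to 127.5 in Cy3, against medians of the negative controls of 68.4 to 74.1 and 96.3 to 104.4. Names came from the RefSeq accession through the gene table of GRCm38.p6 for 22072 probes and from the files otherwise. The brightest probe stood for a gene, and 6225 genes had more than 1 kept probe. The genome build of probe coordinates is not given in the sources used here.

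Genes at a single time were counted by size, a log2 ratio of at least 1 or at most -1 in both orientations. Early and late genes were those that passed this rule upward at any time and were at least 2-fold apart between 1 h and 4 h within both orientations. The mean response (2 residual degrees of freedom) and the slope per doubling of time (1 residual degree of freedom) were tested with lmFit and eBayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Nothing states that the time points came from separate cultures, and p-values then measure only the spread between these samples. List medians were set against 10000 random lists of the same size, matched in 10 bins of signal.

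In simulated data of 22210 genes the control had no spread, and a changed gene had the same change at all times. Under these conditions, which are simpler than the data, the mean test recovered 100% of changes of 1.5 and of 0.75 with 18 false calls. The size rule at 1 h passed 99% of changes of 1.5, 0% of those of 0.75 and 1 unchanged gene. Slopes were simulated as straight lines in log2 time, also with no control spread. The slope test recovered 100% of slopes of 1 and 99% of slopes of 0.5 with 21 false calls. In 20 simulations with no effect and a shared control of equal spread the mean test called 699 to 1452 genes, of which a median of 1 reached a mean of 1, and 0 to 66 genes had a slope. With no control spread the median was 1 call.

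Deviations of same-numbered arrays from their time means correlated at 0.781 to 0.855 across genes. With 2 arrays per time point this mirrors one dye effect per gene. The numbers mark dye orientation per the labels. Over all genes, the opposite orientations of a time point correlated at 0.295 to 0.352, and over the genes passing the size rule at 0.983 to 0.987. That rule picks genes on which both orientations are large in the same direction. The second range is therefore raised by the selection and is no measure of reproducibility.

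Named genes were chosen by a rule set before the data were examined, with 12 per direction at each time and for each test, only gene symbols, up to 4 per list by size, any list member by its values, and Il1r1 and the housekeeping genes always. The pattern that recognises gene symbols was corrected after values had been seen, which brought H2-T10 into the 12 rising slopes in place of Snai2. Alternatives set in advance were the processed signals, no background correction, an offset of 16, median centring, Aquantile scaling, the value table, the mean of a gene's probes, no filter or a stricter filter, each replicate or time left out, other size rules, a replicate block and another variance model. Figures were drawn with matplotlib 3.10.9.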

Results

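The data describe how the transcriptome of mouse dermal fibroblasts, the matrix-producing cells of the skin, stood after 1, 2 and 4 h with interleukin-1 (IL-1) at 20 ng/ml. IL-1 is a cytokine that activates the NF-kB and MAP kinase pathways through its receptor. The cells came from C57BL/6 mice. Each of the 6 two-colour arrays compared RNA of treated cells with RNA of untreated cells (0 h), and each of the 3 time points was hybridised on 2 arrays with the dyes exchanged. The 2 arrays of a time point carried the same RNAs and were counted as 1 sample per time point. After filtering, 22210 genes were measured, of which 15250 carried a gene symbol. Values are log2 ratios of treated over untreated, in the direction given by the dyes in the labels, averaged over both dye orientations. The error given is the distance of either orientation from that average, which is a technical error only. A gene's own dye effect is part of this distance but cancels in the average, so the distance is not the error of the average itself. The median of this distance over all genes and times was 0.0622, and its 95th percentile was 0.197. The number of arrays limits the precision, and each time point is represented by 1 treated RNA.

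The first comparison asked which mRNAs differed from the untreated level 1 h after IL-1. The chemokine Cxcl1, a neutrophil attractant, stood highest, at a log2 ratio of 6.21 ± 0.039, or 73.9-fold. The chemokines Ccl20 (3.82 ± 0.33, 14.1-fold) and Cxcl5 (3.62 ± 0.090, 12.3-fold) were also higher, and so were regulators of NF-kB. Nfkbiz, a nuclear cofactor, was at 3.37, Nfkbia, which encodes the inhibitor IkB-alpha, at 3.02, Bcl3 at 2.46 and the deubiquitinating enzyme Tnfaip3 (A20) at 2.36. The monocyte attractants Ccl2 and Ccl7 were at 2.72 and 2.36, the cytokine Il6 at 2.51, the adhesion molecule Icam1 at 2.34 and the transcription factor Irf1 at 2.21.

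In all, 47 genes were at least 2-fold higher at 1 h in each orientation and 2 were at least 2-fold lower. The lower genes were the zinc finger gene Zfp503 (-1.18) and Id4 (-1.09), an inhibitor of basic helix-loop-helix factors. On the fixed lists, 8 of 19 measured NF-kB pathway genes, 9 of 21 chemokines and 8 of 30 immediate early genes were higher. The last included Ier3 (1.85), Nr4a1 (1.64), Klf10 (1.39), Junb (1.33) and Egr2 (1.28). Egr1 (-0.11) and Fos (-0.26), which also belong to that list, were not 2-fold different. The Fos probe was dim (mean log2 signal 6.70), so its small value does not show that Fos did not respond. With 1 sample there was no test at a single time point. In the dye direction, 0 genes reached the same size as Cy5 over Cy3 and 12 as Cy3 over Cy5 on both arrays of each time point. Such genes have opposite signs of treated over untreated in the 2 orientations and cannot pass the size rule. These counts describe dye effects and are no measure of false passes of that rule. Centring each array on its median in place of the intensity-dependent correction gave 24 higher genes, 23 of them among the 47, and 0 lower, the scanner's processed signals gave 4 lower and the mean of a gene's probes gave 1 lower. On single arrays, 72 genes were higher and 5 lower without replicate 1, and 16 were lower without replicate 2.

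The second comparison set 2 h against the untreated cells. Cxcl1 stood at 5.49 (44.8-fold), Cxcl5 at 4.34 (20.3-fold) and Ccl20 at 3.67 ± 0.36. Il6 was at 2.96 (7.80-fold), Nfkbia at 2.65, Ccl2 at 2.54, Icam1 at 2.44 and Ccl7 at 2.32. Angptl4, a secreted inhibitor of lipoprotein lipase, was at 2.32, Bcl3 at 2.24, the transcription factor Cebpd at 2.08 and Cxcl3 at 2.07. In all, 40 genes were at least 2-fold higher and 0 at least 2-fold lower, with 33 of the higher genes shared with 1 h. Simulated unchanged samples against a shared control gave a median of 0 shared genes, but their lists held a median of 1 gene. A large overlap was therefore not possible there. Independent lists of the observed sizes would share 0.0846. Part of the excess may come from the shared untreated RNA. The NF-kB pathway list had 9 of 19 genes higher and the chemokine list 8 of 21, whereas the immediate early list had 3 of 30 (Ier3, Cebpb and Cebpd). The number higher was 82 with the scanner's processed signals and 21 with median centring, and the number lower was 4 with the former. Without replicate 1 the counts were 67 higher and 4 lower, and without replicate 2 the number lower was 16.

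At 4 h the chemokines Cxcl1 and Cxcl5 were at 4.84 (28.7-fold) and 4.71 (26.2-fold). Il6 and Ccl2 were both at 2.73, and so was Ccl20. Serpina3g, a serine protease inhibitor, was at 2.55, Ccl7 at 2.34, Cxcl3 at 2.17, Angptl4 at 1.89, Nfkbia at 1.87, Icam1 at 1.83 and the NF-kB subunit Relb at 1.42. In all, 30 genes were at least 2-fold higher and 0 lower, and 21 genes were higher at all 3 times. The overlap with 1 h was 21 genes and that with 2 h was 25, against independent expectations of 0.0635 and 0.054. The simulated medians were 0, but the simulated lists held a median of 1 gene and could not show a large overlap. The scanner's processed signals gave 57 higher and 5 lower genes, an offset of 16 gave 47 higher, and median centring gave 13 higher. Without replicate 1 the counts were 50 higher and 2 lower, and without replicate 2 the number lower was 13.

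Limits apply to single genes. The Ccl2 spot was saturated on 3 of the 6 arrays in the treated channel, which can hold its ratio down. The Rplp0 and S100a4 spots were saturated on 6 arrays in the untreated channel and on 3 in the treated channel, so their ratios are not measured values. The spots of Acta2, Tagln, Myl9, Ccn2, Timp1, Col1a1, Col1a2 and Vim were saturated on 3 arrays in each channel. The untreated signal was well above background on only 1 array for Csf2, 4 for Cxcl10 and 5 for Zc3h12a. The added offset of 50 compresses ratios of dim genes, and the Csf2 log2 ratio at 1 h was 1.64 with it, 2.58 with an offset of 16 and 4.44 with the scanner's processed signals. With the latter, Cxcl10 went from 1.63 to 3.76 at 1 h and Zc3h12a from 1.91 to 3.46. Cxcl2 (1.87 to 3.36), Egr3 (1.01 to 2.27) and Atf3 (1.18 to 2.16) also grew at 1 h, so the sizes of these responses are not settled. Folds and their order depended on the processing as a whole. With the scanner's processed signals Cxcl1 stood at 113-fold at 1 h, Ccl20 at 34.7-fold and Icam1 at 9.49-fold where the values used here gave 5.07-fold, and the log2 ratio of Icam1 (3.25) then lay above that of Nfkbia (3.08). Of 12 genes that were higher and had several probes, 7 had a probe under the size threshold (Birc3, Cebpb, Fas, Icam1, Nfkb1, Rnd1 and Vcam1). At 1 h the other probes of Rnd1 (0.12 and 0.015), Fas (-0.019) and Birc3 (-0.0025) were near 0, so the values of these genes rest on 1 probe each. For Nfkb1 the probes also differed in timing, since a second probe gave 1.36 at 1 h and 0.63 at 4 h where the brightest gave 0.78 and 1.04.

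**Figure D1:**
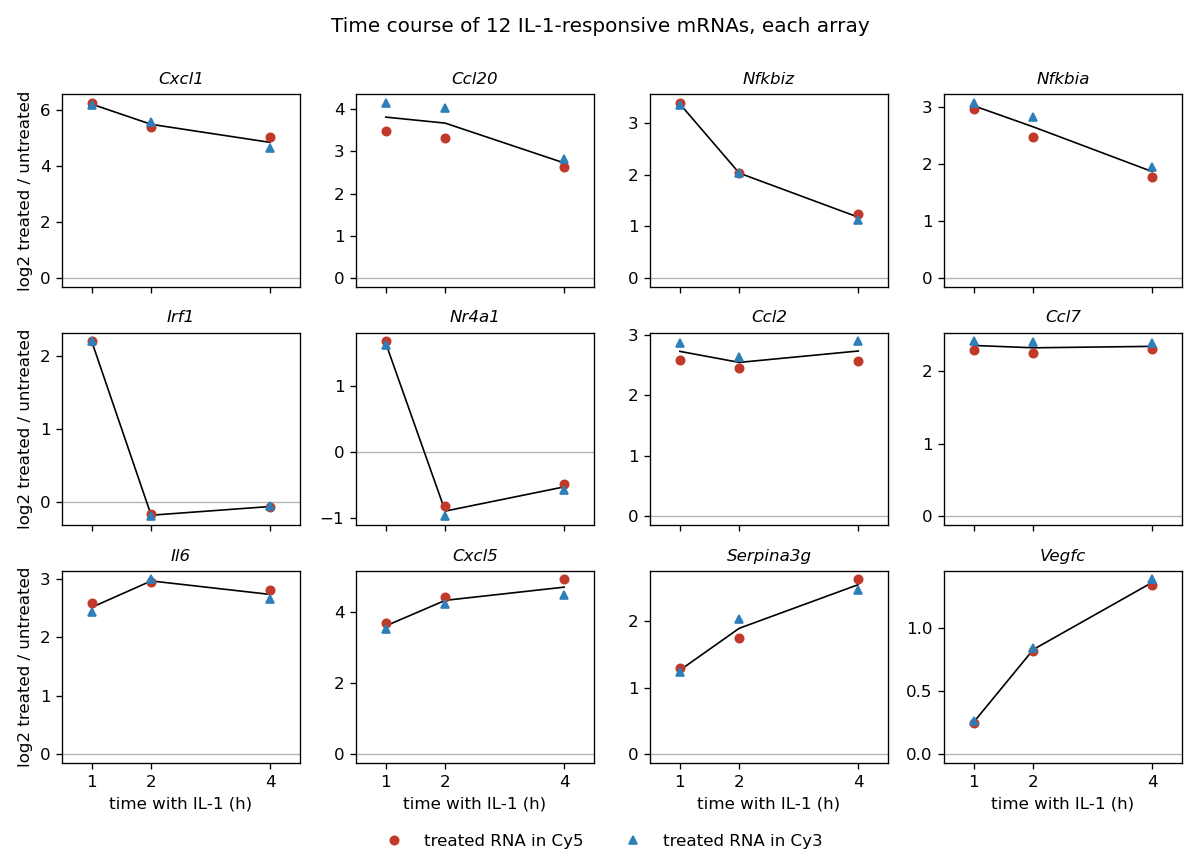
Log2 ratio of treated over untreated (vertical axis, own range per panel) against hours with IL-1 for 12 genes, with circles for the array with treated RNA in Cy5, triangles for the array with it in Cy3, and a line for their mean. Irf1 stood at 2.21 at 1 h and at -0.18 at 2 h, Ccl7 stayed between 2.32 and 2.36, and Vegfc went from 0.26 at 1 h to 1.36 at 4 h.

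The arrays of 1 h and 4 h were then set against each other within each dye orientation. The untreated RNA cancels from this comparison only if 1 extract served all arrays, which is not stated. Of the 59 genes higher at any time, 19 were at least 2-fold higher at 1 h than at 4 h in both orientations. They were the NF-kB regulators Nfkbia, Nfkbie, Nfkbiz, Bcl3 and Tnfaip3, the chemokines Cxcl1, Cxcl2 and Cxcl10, the transcription factors Atf3, Bhlhe40, Egr2, Irf1, Junb, Klf10 and Nr4a1, and Cish, Gadd45b, Kdm6b and Rnd1. Irf1 went from 2.21 at 1 h to -0.18 at 2 h, and its second probe from 1.17 to -0.0056. At least 2-fold higher at 4 h than at 1 h were 2 genes, Serpina3g (1.27, 1.90 and 2.55) and the lymphatic growth factor Vegfc (0.26, 0.83 and 1.36). The scanner's processed signals gave 31 early and 5 late genes, and median centring gave 9 early genes.

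The mean response over the 3 treated samples was tested against 0 with limma. Differences between times count as spread in this test, so a gene high mainly at 1 h can miss the threshold. Tnfaip3, at 2.36 at 1 h, did so (limma adjusted p = 0.0522). The genes with the largest rises were Cxcl1 (mean log2 ratio 5.51 ± 0.23, SE, n = 3, limma adjusted p = 0.000605), Cxcl5 (4.22), Ccl20 (3.41), Il6 (2.74), Ccl2 (2.66), Nfkbia (2.51), Ccl7 (2.34 ± 0.022, limma adjusted p = 1.84e-06), Icam1 (2.21), Nfkbiz (2.19), Bcl3 (2.01), Angptl4 (1.95) and Cxcl3 (1.94). Il1r1, the IL-1 receptor, rose by 0.54. Among genes that fell, Zfp503 was at -0.96, the RNA-binding protein gene Taf15 at -0.89, the matrix protease gene Adamts1 at -0.88, the insulin receptor substrate Irs1 at -0.81, Id4 at -0.76, the lamin gene Lmnb1 at -0.69, Adamts5 at -0.69, Raly at -0.67, the ephrin receptor Ephb3 at -0.65, and Snai2, Npm3 and Flrt3 at -0.63. The rises were larger than the falls. Of the genes past the threshold 39 had a mean of at least 1, all of them up, while 138 were up by at least 0.5 and 25 down by at least that much.

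Past the threshold of adjusted p lay 2338 genes up and 2394 down, and 96.6% of these 4732 had a mean below 0.5 in size. Such small shifts depended on the processing, with 750 up and 587 down from the scanner's processed signals, 1124 up and 5737 down with median centring, and 472 up and 342 down without the 2 h sample. Without replicate 2 the number up was 4745, and without replicate 1 the number down was 4274. The test leaves out the spread of the untreated culture, and simulated unchanged samples that shared a control of equal spread gave a median of 1073 calls.

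The slope of the log2 ratio per doubling of time was tested with limma as well. It is free of the untreated RNA only if 1 extract served all arrays. Among genes past the adjusted threshold, the steepest falling slopes were those of Nfkbiz (-1.10 ± 0.062, SE, n = 3, limma adjusted p = 0.00512), Tnfaip3 (from 2.36 at 1 h to 0.35 at 4 h), Egr2 (-0.87), the GTPase gene Rnd1 (-0.83), the cytokine signalling inhibitor Cish (-0.80), Cxcl2 (-0.74), Cxcl1 (-0.68), Gadd45b (-0.66), Egr3 (-0.62), Cxcl10 (-0.61), Atf3 (-0.60) and the histone demethylase gene Kdm6b (-0.59). The slopes of Irf1 (-1.14), Nr4a1 (-1.09) and Klf10 (-0.81) did not pass. The test fits a straight line in log2 time, so a drop between 1 h and 2 h alone counts partly as spread. Rising slopes past the threshold were led by Serpina3g (0.64 ± 0.027, SE, n = 3, limma adjusted p = 0.00153), Vegfc (0.55), Cxcl5 (0.55), Slco3a1 (0.44), Serpinb2 (0.44), the histocompatibility gene H2-T10 (0.43), Cyp7b1 (0.41), Plscr1 (0.41), Ttc39c (0.41), Ccl11 (0.40), Slpi (0.35) and the stromelysin gene Mmp3 (0.35). Snai2, also past the threshold (0.34), rose towards the untreated level from -1.01 at 1 h to -0.33 at 4 h.

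In all, 45 genes had a rising and 54 a falling slope. Fitting the 6 arrays unaveraged treats the 2 arrays of a time point largely as separate samples. With dye orientation in that fit, the counts were 240 rising and 235 falling. They were 9 and 15 without replicate 1, 13 and 19 without replicate 2, 216 and 239 with no background correction, and 237 and 177 with median centring. The calls ended at the adjusted threshold with the scanner's processed signals, with an offset of 16 and with limma's trended robust variance (0 genes in each direction, limma), where 2023, 2082 and 2371 genes had an unadjusted p under 0.05, against 2314 with the settings used here.

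Gene lists fixed before the data were examined group the response by function. For scale, 2338 of all 22210 measured genes rose and 2394 fell by the same test. A list count near that share does not set the list apart from all genes. In the NF-kB pathway list 16 of 19 measured genes rose in the mean response and 0 fell (17 up when adjusted over the list alone), including Relb (1.83) and Nfkb2 (1.07). Its median log2 ratio was 0.78, 0.98 and 0.55 at 1, 2 and 4 h, above all 10000 random lists matched on signal at each time. Such ranks were not particular to this list. Chemokines were also at percentile 100 at each time, and the fibroblast matrix list was at 100, 100 and 99.89. The direction of the matrix list did not hold with median centring. In the chemokine list 15 of 21 rose and 1, Cxcl14 (-0.36), fell (15 and 1 over the list alone). Of the cytokines and growth factors, 12 of 33 rose and 3 fell (12 and 4 over the list alone), with Vegfc at 0.81 and Csf1 at 0.80, while Bdnf fell by 0.57. Tnf, Il1a and Lif were at 0.029, 0.049 and -0.00083 in the mean and did not pass. For the immediate early list 8 of 30 rose and 3 fell (9 and 3 over the list alone), and its median went from 0.58 at 1 h to 0.051 at 2 h and 0.040 at 4 h. That median at 2 h turned to -0.073 with median centring.

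Genes that restrain signalling moved in both directions. Among MAP kinase feedback and mRNA decay regulators 7 of 22 rose and 5 fell (7 and 6 over the list alone). The RNase gene Zc3h12a rose by 1.64, Rgs16 by 1.22 and Errfi1 by 0.94, while Spry1 was at -0.57 and Dusp1 at -0.32. Of 12 cytokine feedback inhibitors 3 rose, among them Cish (1.01) and Socs3 (0.47), and 2 fell (4 and 2 over the list alone). In the IL-1 and Toll receptor list 8 of 21 rose and 1 fell (9 and 3 over the list alone), with Tlr2 at 1.09, the adaptor kinase Ripk2 at 0.79 and Il1rl1 at 0.67. Of the apoptosis and survival genes 7 of 20 rose and 1 fell (9 and 3 over the list alone), including the death receptor Fas (1.56) and Casp4 (0.93).

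Among adhesion molecules 8 of 15 rose and 2 fell (8 and 3 over the list alone), led by Icam1 and Vcam1 (1.29), and the list median turned from 0.15 to -0.013 at 2 h with median centring. In the list of prostaglandin, nitric oxide and redox enzymes 8 of 18 rose and 3 fell (9 and 3 over the list alone), and 0 were 2-fold higher at any time. That 0 depended on the processing. With the scanner's processed signals Ptger2 averaged 2.66-, 4.66- and 2.85-fold at 1, 2 and 4 h, and Gch1 averaged 2.39-fold at 4 h. The inducible cyclooxygenase Ptgs2 was at 0.54, 0.66 and 0.44 at 1, 2 and 4 h, Ptges was at 0.53 in the mean, and Nos2 (0.01) did not pass. Of the matrix proteases and their inhibitors 9 of 25 rose and 4 fell (9 and 6 over the list alone), with the saturated Timp1 among the 9, and the list median at 4 h turned from 0.059 to -0.036 with median centring. Mmp3 stood at 0.22, 0.41 and 0.91 and Mmp9 at 0.30, 0.52 and 0.89, while Adamts5 was at -0.33, -0.75 and -0.97. In the fibroblast matrix list 12 of 27 rose and 4 fell (18 and 4 over the list alone), with the hyaluronan synthase Has1 at 0.70 and decorin (Dcn) at 0.46. The medians of the matrix list lay between 0.086 and 0.13 and turned to between -0.051 and -0.014 with median centring, so the list had no direction that held under both scalings.

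Of 13 contractile and serum-response genes 4 rose (4 over the list alone), and 4 others (Acta2, Tagln, Myl9 and Ccn2) were saturated as described. The list median turned from 0.094 to -0.072 at 1 h with median centring, but the former is the value of the saturated Ccn2, so the list gave no measured direction. Among 25 interferon-responsive genes 4 rose (4 over the list alone). Only Irf1 was 2-fold higher at any time with the settings used here. Its mean of 0.65 did not pass (limma adjusted p = 0.379), as differences between times count as spread. With the scanner's processed signals Irf5 averaged 2.44- and 2.52-fold at 1 and 2 h. Ifit1 (-0.06) and Isg15 (-0.05) did not pass. Of the TGF-beta, BMP and Notch target regulators 5 of 22 rose, with Gadd45b at 0.97, and 6 fell, with Id4 at -0.76 and Gadd45g at -0.57 (7 and 9 over the list alone). Of 17 circadian clock genes 4 rose and 2 fell (4 and 2 over the list alone), and of 28 cell cycle genes 5 rose and 7 fell (5 and 11 over the list alone), with Ccne2 at -0.54. Of 13 housekeeping genes 4 rose (6 up and 1 down over the list alone), each by 0.30 or less, and 0 were 2-fold higher or lower. One of those 4, Rplp0, was saturated as described, and another, Ppia, turned to -0.053 with median centring.

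Among fibroblast markers 5 of 16 rose and 1 fell (5 and 2 over the list alone), with the saturated S100a4 among the 5. Twist2 rose by 1.26 and Lrig1 by 0.81, whereas the related factor Twist1 was at -0.33. Markers of other cell types that a skin culture can hold gave no 2-fold value at any time. Of these, 2 of 19 macrophage and leukocyte markers rose and 1 fell (2 and 1 over the list alone), 0 of 8 mast cell and 0 of 11 endothelial markers passed (0 over each list alone), 1 of 12 keratinocyte markers fell (1 over the list alone), 1 of 8 melanocyte and Schwann cell markers rose and 1 fell (1 and 1 over the list alone), and 2 of 7 smooth muscle and adipocyte markers rose and 2 fell (2 and 3 over the list alone).

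**Figure D2:**
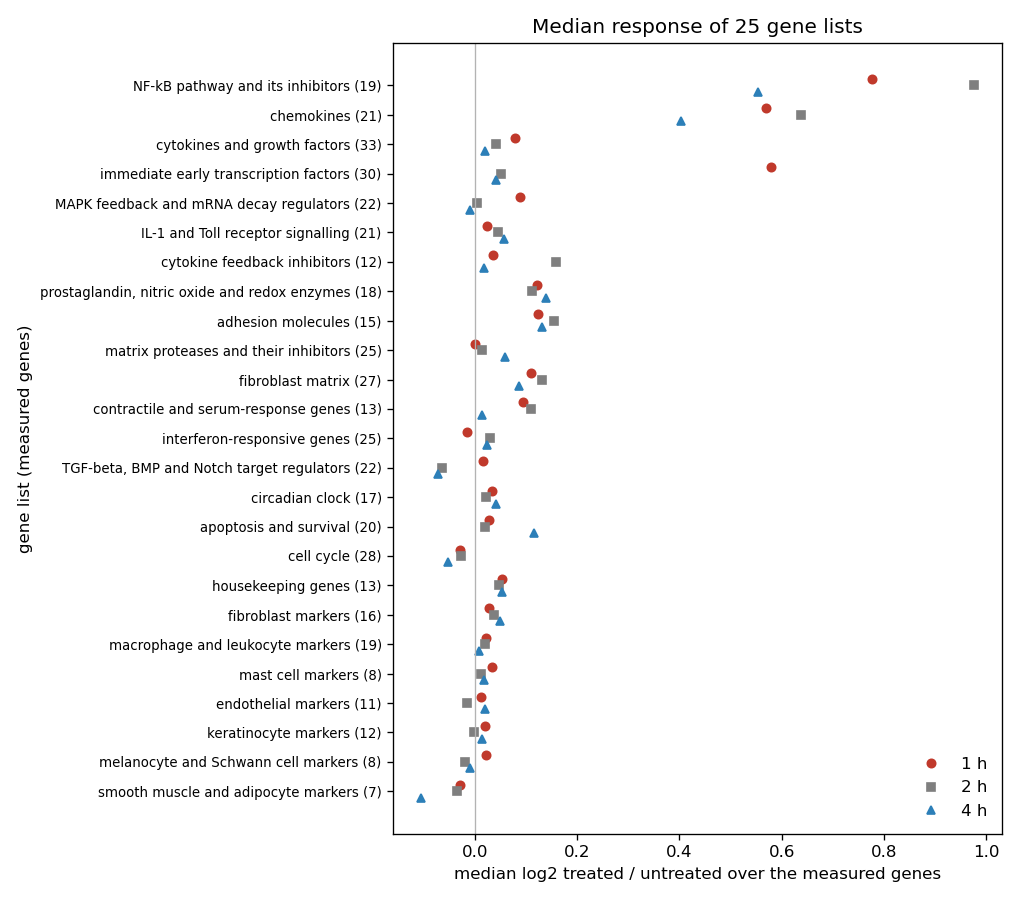
Median log2 ratio of treated over untreated (horizontal axis) for the 25 gene lists (vertical axis, measured genes in parentheses), with circles for 1 h, squares for 2 h and triangles for 4 h. The NF-kB pathway list lies farthest to the right at 0.78, 0.98 and 0.55, and the immediate early list stands at 0.58 at 1 h and at 0.051 at 2 h, a value that turned to -0.073 with median centring.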

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

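The tests below were chosen after the results were seen, except the share of calls that kept their sign with the processed signals. The test of upward calls of at least 0.5 was chosen before its result, but its limit of 0.5 was set after the data were seen. Genes at least 2-fold higher at 1 h in both orientations lay below the untreated level in both orientations at a later time. Irf1 was at -0.18 at 2 h and -0.0652 at 4 h, Klf10 at -0.20 and -0.22, and Nr4a1 at -0.90 and -0.53. At 4 h Egr2 was at -0.46, Bhlhe40 at -0.12, Kdm6b at -0.0482 and Atf3 at -0.0289. The last 2 are smaller in size than the median technical error of 0.0622 over all genes and times, which includes dye effects that cancel in an average. Their own technical errors at 4 h were 0.024 each. The Atf3 log2 ratio at 4 h turned to 0.022 with the processed signals. The Irf1 log2 ratio at 4 h turned to 0.0018 with the mean of its probes. The limma slope test found 99 genes whose ratio changed with time, among them Egr2, Atf3 and Kdm6b. Simulations with no effect gave up to 66 such calls, and with the processed signals, an offset of 16 and the trended robust variance limma called 0 genes (2023, 2082 and 2371 at an unadjusted p under 0.05). Irf1 (limma adjusted p = 0.237), Nr4a1 (0.327), Klf10 (0.190) and Bhlhe40 (0.0786) did not pass it. The slope test fits a straight line in log2 time, and departure from that line counts as spread. Failing it therefore does not show that the difference between times was small. These genes are among the 19 early genes by size, but their difference between times was not established by a test.

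Nr4a1 was above the untreated level at 1 h and below it at 2 h. A bad spot on one slide is argued against, because the 2 orientations gave differences between 1 h and 2 h of which the smaller was 2.49. Whether immediate early mRNA was already raised in the untreated culture stays open. Such a rise would lower the whole list at later times, and the immediate early list had its median at percentile 95.8 of random lists at 4 h, which does not decide for a single gene. A transient induction followed by repression may also account for the pattern, as a hypothesis that was not tested.

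The mean-response test called 4732 genes, most by small amounts. With the processed signals 99.98% kept their sign, but those signals carry a dye correction of their own, and with median centring 89.9% did. Of the upward calls 37% were still called up with median centring, and of those with a mean of at least 0.5 the share was 100%, but 2323 of 2394 downward calls were kept, so a common downward shift is not told apart from a loss of the intensity-dependent correction. Deviation of the single untreated RNA stays open for the bulk, since the simulated median of 1073 calls assumes its spread. If 1 extract served all arrays, it cannot produce the difference of at least 2-fold between 1 h and 4 h in 21 genes passing the size rule, but with separate extracts this stays open too.

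Ptgs2, a well-known IL-1 target, was at 0.66 at 2 h, and a second probe gave 0.58. Compression by the offset is argued against by 0.68 with the processed signals. Saturation is argued against as well, with the Ptgs2 probe saturated on 0 treated channels. A ranking of the untreated Ptgs2 signal among genes was computed once and left out, because levels of different probes cannot be compared. A high level already present in the untreated cells therefore stays untested, and no biological explanation was tested.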

How the results depend on the processing

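The 1.5-fold rule, the limit of 0.5 on the mean and the list medians under other settings were chosen after seeing the data. Aquantile scaling changes no ratio by construction, and no filter and the stricter filter left every count within 1.5 times, as the scanner's p did for the counts at single times, for which alone it was run. The cause of the changes below was not tested. The processed signals, and the authors' value table with identical counts, gave 82 and 57 genes higher at 2 and 4 h, 4, 4 and 5 lower at 1, 2 and 4 h, 31 early, 5 late, 750 up and 587 down in the mean, and 0 rising and 0 falling (limma; 2023 at an unadjusted p under 0.05). They shared 47, 40 and 30 higher genes with the main setting at the 3 times, which is all of them. No background correction gave 216 rising and 239 falling. An offset of 16 gave 47 higher at 4 h, 1 lower at 2 h, and 0 rising and 0 falling (limma; 2082 unadjusted). Median centring moved the median of all genes from 0.0033 to -0.034 at 1 h and gave 24, 21 and 13 higher, 0 lower at 1 h, 9 early, 1124 up and 5737 down, 237 rising and 177 falling. The mean of a gene's probes gave 1 lower at 1 h, and the mean of both orientations 1 lower at 2 h. The trended robust variance gave 0 rising and 0 falling (limma; 2371 unadjusted). At 1.5-fold, 91, 95 and 82 genes were higher and 7, 14 and 13 lower. With a mean of at least 0.5, 138 were up and 25 down.

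Leaving out 1 replicate at a time, the ranges were 53 to 72, 42 to 67 and 42 to 50 higher at 1, 2 and 4 h, 5 to 16, 4 to 16 and 2 to 13 lower, 19 to 23 early, 2 to 3 late, 9 to 13 rising and 15 to 19 falling. Leaving out a replicate or a time sample gave 472 to 4745 up and 342 to 4274 down, with the lowest counts without the 2 h sample. The mean of Rplp0 was -1.17 without replicate 2, and its spot was saturated on 6 arrays in the untreated channel and on 3 in the treated channel. The replicate block fitted the 6 arrays unaveraged, with dye orientation as a covariate and time as the correlated block. The within-time correlation was 0.224 for the mean and -0.126 for the slope. The 2 arrays of a time point were thus treated largely as separate samples, which they are not. This fit gave 2871 up, 2933 down, 240 rising and 235 falling, and these higher counts are no independent support. It ended no call of a named gene. A slide block was not run, because each array lay on its own slide.

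For named genes at single times, no value that passed the size rule changed sign in any setting for which such values were computed. They were not computed for the filter settings. A value passes only if both orientations lie at least 1 from 0 in the same direction. Leaving out a replicate therefore could not change its sign, and another setting would have to move it by at least 1. Of 89 named genes past the mean threshold, 44 no longer passed with the processed signals, 17 with the offset of 16, 46 without the 2 h sample and 3 with median centring, and 44 of 44 slopes no longer passed with the processed signals. With median centring the means of Ppia (-0.053) and Rplp0 (-0.034) reversed, as did list medians of the adhesion molecules (-0.013 at 2 h), contractile genes (-0.072 and -0.073 at 1 and 2 h), fibroblast matrix (-0.045, -0.051 and -0.014), immediate early genes (-0.073 at 2 h) and matrix proteases (-0.036 at 4 h). Signal over background limits the dim genes. Median signals were 121.8 to 137.7, and medians of the negative controls reached 104.4.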

Other observations

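Chemokine genes that lie next to each other gave different values. In the cluster on chromosome 5 (coordinates as the files give them, build not given in the sources used here), Cxcl5 at 90058767 to 90058826 was at 3.62, 4.34 and 4.71 after 1, 2 and 4 h, and Cxcl3 at 90085256 to 90085315 was at 1.59, 2.07 and 2.17. Between them Ppbp was at -0.015, 0.0040 and 0.090 and Pf4 at -0.079, 0.046 and 0.021, both well above background on 6 arrays in each channel. Cxcl15 lies next to Cxcl3 and was not well above background in either channel on any array, while Cxcl1 at 90209491 to 90209550 and Cxcl2 at 90222180 to 90222239 had the early profile. Farther along the chromosome Cxcl10 was at 1.63, 1.35 and 0.40, and its neighbours Cxcl9 and Cxcl11 were well above background on 0 and 1 arrays in each channel, so no ratio was measured for them. On chromosome 11 Ccl2 and Ccl7 were above 2 at all times, and the adjacent Ccl11 was at 0.11, 0.53 and 0.91. The untreated Ccl11 signal was well above background on 5 arrays, and the processed signals gave 0.40, 1.62 and 2.17. Ccl12 and Ccl8 stayed between -0.085 and 0.32, and Ccl1 was well above background on 1 array in the untreated and 3 in the treated channel. The offset of 50 holds ratios of dim probes near 0, so small values here do not show that a gene did not respond. Ppbp, Pf4 and Ccl1 were chosen after their values were seen.

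Related genes also parted. Twist2 was at 1.06, 1.37 and 1.36, and Twist1 at -0.11, -0.33 and -0.55. Among proteases of one family, Adamts4 was at 0.76, 0.54 and 0.20, whereas Adamts1 was at -0.74, -1.07 and -0.83. Among NR4A receptors Nr4a1 and Nr4a2 were at 1.64 and 0.71 at 1 h, and Nr4a3 was at 0.02. Of the AP-1 genes Junb was at 1.33 and Fosl2 at 0.92 at 1 h, while Fos was at -0.26 and Fosb at 0.09. The Fos probe was dim (mean log2 signal 6.70), and the offset holds ratios of dim probes near 0.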
